A study of Mus musculus with 10 samples.

How the data were processed

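The series holds 10 poly(A)-selected RNA-seq libraries of cultured primary mouse lung fibroblasts, 5 wild type and 5 Mrc2 knockout, sequenced on an Illumina NovaSeq instrument, per the labels. The deposited table holds raw read counts per Ensembl gene, with 1 column per library and 54532 genes. The submitters' processing notes name STAR 2.5, HTSeq 0.6.1, DESeq2 2 and the mm10 genome build, without their roles. The annotation release, the read length and the strand setting are not given in the sources used here. The values were whole numbers, with 0 unnamed or summary lines. Coordinates are those in the deposited table. Of its gene IDs, 54495 were also in the mm10 annotation used for reference, 53585 with the same chromosome, start and end. No 2 libraries agreed within sampling noise: the lowest chi-square per degree of freedom of any pair was 19.1. The total count per library ranged from 19603933 to 29944615, and 3 counts corresponded to 0.100 to 0.153 CPM. Molecular identifiers are not mentioned in the sources used here, and this floor covers counting error only.

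Groups came from the genotype label and replicate numbers from the titles. The tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Low-count genes were removed with filterByExpr, which left 14360 of 28582 genes with a count above 0. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, no covariate and no replicate block. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. CPM values used TMM-scaled library sizes, and log2 CPM used a prior count of 2. The biological coefficient of variation was 26.2% and the prior degrees of freedom were 3.7. The edgeR code was tested on simulated counts for 14168 genes, each drawn independently with its spread as estimated in the comparison. It called 20% of genes changed by 1.5-fold, 58% of those changed by 2-fold, 94% at 4-fold and 100% at 8-fold, with 10 false among 146 calls.

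The 31 gene lists covered the cell cycle, p53 and senescence, collagen and matrix, collagen uptake and lysosomes, contractility and signalling, fibroblast subtypes, other cell types and stress or metabolic responses. All list genes were matched to the table, 5 of them by gene ID. Each list was tested with camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 31 lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the mean list score, where a score is the mean log2 CPM of the members after centring each gene over the 10 libraries. With preset correlation 14 lists were called (9 higher, 5 lower) and 0 with estimated correlation, where the lowest adjusted p was 0.460. Fry called 0 lists (lowest adjusted p = 0.0929; 7 had an unadjusted p under 0.05), and 5 lists had an exact permutation p under 0.05 (lowest adjusted p = 0.197).

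The genes named were Mrc2; among called genes with a mean log2 CPM of at least 1 and no overlap between groups, up to 8 with the largest rise and 8 with the largest fall; the 4 others with the smallest adjusted p; examples from up to 4 members with the smallest adjusted p in each list described; and 16 genes set in advance (Mki67, Ccnd1, Cdkn1a, Cdkn2a, Col1a1, Col1a2, Col3a1, Fn1, Acta2, Mmp2, Mmp14, Ctsk, Ctsb, Pdgfra, Mrc1, Pla2r1). Of 74 genes looked at, 15 overlap another tested gene: Ccnd1, Cdkn1a, Col1a2, Ctsb, Prc1, Kif20a, Col5a1, Loxl3, Adamts2, Vcan, Itga1, Lamp1, Myh9, Cygb and Spp1. Their values are less certain, since the strand setting of the counting is not given.

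Alternatives tried were other size factors, other low-count filters, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, a covariate of Y-linked expression, 1 surrogate variable (sva 3.50.0), the removal of chromosome 11, and other list tests. The exact permutation of list scores, a length and GC offset (also without knockout replicate 5), the length slope or the leukocyte score as a covariate, the removal of the 3 libraries of lowest length slope, and limma-voom with sample quality weights were added after the data were seen. GC content was that of the longest transcript of each gene in the mm10 reference annotation and was available for 99.96% of the tested genes. For counts of splits, 100 splits of the libraries were used, the real one included and the others drawn with a fixed seed.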

Results

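RNA was sequenced from primary lung fibroblasts of mice, cultured without any added stimulus in medium with 10% fetal bovine serum. The series compared 5 wild-type cultures with 5 cultures labelled as knockout of Mrc2, which encodes an endocytic receptor that binds collagen and carries it to lysosomes for breakdown. The question named by the series is whether loss of this receptor alters the proliferation of lung fibroblasts. Each library was a poly(A)-selected RNA-seq library, and the total count per library ranged from 19603933 to 29944615 reads assigned to genes. All 10 libraries carried the same batch label, though their library names fall into separate runs by genotype. Xist was counted at most 4 times in any library and the Y-linked gene Ddx3y lay between 60.8 and 112 CPM, so every library had the expression pattern of male cells. The titles number the libraries as biological replicates, and nothing more says that they came from separate animals. The p-values therefore measure the spread between these samples.

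Mrc2 (ENSMUSG00000020695; mm10 chromosome 11, 105292643 to 105351139, plus strand, protein-coding) was strongly lowered in every knockout library. Its level was 843 ± 176 CPM in wild type and 242 ± 30.4 CPM in knockout (SD, n = 5 each), and the knockout mean was 28.7% of the wild-type mean. The lowest wild-type library had 568 CPM and the highest knockout library 282 CPM, so all 10 libraries matched their genotype labels. In edgeR's quasi-likelihood test the log2 fold change was -1.80 (SE 0.17, Benjamini-Hochberg adjusted p = 0.0029). Of the settings that kept Mrc2, only the replicate block, with fewer residual degrees of freedom, lost its call. The remaining reads show that transcript from the locus was still made. Counts per gene do not tell which exons those reads came from. The closest relatives of Mrc2 did not pass the test. Mrc1, the macrophage mannose receptor, had a log2 fold change of -0.08 (SE 0.38, adjusted p = 0.939 by edgeR), and Pla2r1, a phospholipase A2 receptor of the same family, 0.00 (SE 0.24, adjusted p = 0.994 by edgeR). Both signs turned when single libraries were left out, with ranges of -0.44 to 0.16 for Mrc1 and -0.14 to 0.16 for Pla2r1.

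Besides Mrc2, 1 gene passed the test over all 14360 genes: Crct1, a small cysteine-rich gene of the epidermal differentiation complex (ENSMUSG00000027913; chromosome 3, 93014205 to 93015687). Crct1 fell from 11.96 ± 5.78 to 2.24 ± 0.40 CPM (SD, n = 5 each, log2 fold change -2.41, SE 0.31, edgeR adjusted p = 0.048), and was lower in 5 of 5 knockout libraries than in any wild-type library. With Mrc2 taken out before the adjustment 0 genes passed, so the call of Crct1 rests on Mrc2 being among the genes tested. The next genes by adjusted p did not pass. Tspan18, a membrane tetraspanin, was at 2.59 ± 0.79 CPM in wild type and 7.49 ± 1.14 CPM in knockout (log2 fold change 1.54, SE 0.23, edgeR adjusted p = 0.138; n = 5 each). Npnt, a basement-membrane ligand of integrin alpha 8, was at 68.9 ± 14.99 and 142 ± 23.7 CPM (1.05, SE 0.17, edgeR adjusted p = 0.141; n = 5 each). Ivl, which encodes involucrin, a protein of the cornified envelope, was at 18.6 ± 7.44 and 4.30 ± 1.45 CPM (-2.12, SE 0.34, edgeR adjusted p = 0.141; n = 5 each). The groups did not overlap for any of these 3 genes, and all 3 passed without knockout replicate 5 (edgeR adjusted p of 0.0329, 0.0329 and 0.0332). That library was singled out because leaving it out raised the number of calls. Passing without it, here and below, is therefore no separate support.

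**Figure D1:**
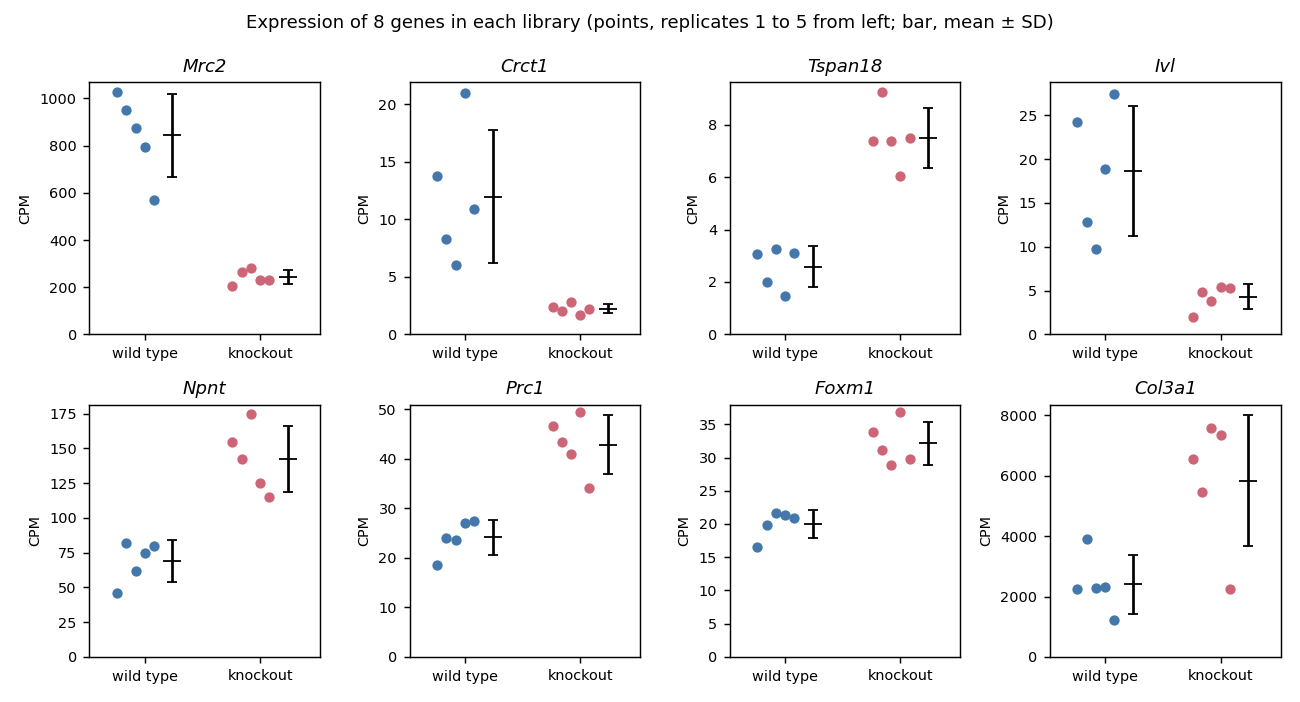
CPM of Mrc2, Crct1, Tspan18, Ivl, Npnt, Prc1, Foxm1 and Col3a1 in each of the 5 wild-type and 5 knockout libraries (points), with the mean and SD of each group (bars). Mrc2 lies at 568 CPM or more in every wild-type library and at 282 CPM or less in every knockout library, and Col3a1 is the panel in which 1 knockout library, replicate 5, lies among the wild-type values.

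The 2 calls were both lower in knockout, and 0 genes passed as higher. Without adjustment 1908 genes had p under 0.05, of which 1032 were higher and 876 lower, where 718 are expected by chance. The 5 values of each group did not overlap for 294 genes, or 2.05% of those tested, where chance gives 0.794%. Both chance values are averages. Genes vary together across the libraries, so such counts can exceed them without an effect of genotype. Splits were not counted for either. In simulated counts with the same spread per gene the test called 58% of genes changed by 2-fold. Changes of that size could be missed here. The simulated genes varied independently, and more of them passed than in the real data, which eases the threshold. The share called in the real comparison could therefore be lower. DESeq2 called 243 genes (146 higher, 97 lower) and limma-voom 1, which was Mrc2. Leaving out knockout replicate 5 raised the edgeR count to 203 (129 higher, 74 lower), and with the length and GC trend of those 9 libraries removed as an offset it was 32 (20 higher, 12 lower). Of the genes called by DESeq2 and those called by edgeR without that library, 96 were shared, all in the same direction, where independent lists of these sizes would share 3.44, though both fits rest on the same libraries. Crct1 lost its call when any of 7 other libraries was left out, with an edgeR adjusted p of 0.177, 0.0515 and 0.119 without wild-type replicates 1, 2 and 5, and of 0.180, 0.286, 0.181 and 0.230 without knockout replicates 1, 2, 3 and 4. The count was then 1. Its call was also lost with limma-voom (0.159), the replicate block (0.189), the Y-linked covariate (0.0748), the surrogate variable (0.0530), the length slope as a covariate (0.0559), the length and GC offset (0.0801, and 0.0516 with knockout replicate 5 also left out) and without chromosome 11 (0.0857), while its log2 fold change stayed between -2.19 and -2.53 in all the fits without the call.

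Genes of mitosis were higher in knockout as a group. All 40 measured members of the list of G2/M and mitosis genes had a log2 fold change above 0, with a median of 0.51 (1.42-fold). The list rose against other genes (camera with a preset correlation, adjusted p = 1.3e-20), but its adjusted p = 0.460 with an estimated correlation, and an exact permutation test of its mean score gave a two-sided p of 0.0317 (adjusted p = 0.197). By edgeR, 25 of the 40 genes were higher when adjusted over the list alone and 0 over all genes tested; 26 had an unadjusted p under 0.05, and DESeq2 called 16. Prc1, which bundles the microtubules of the spindle midzone, was at 24.1 ± 3.58 CPM in wild type and 42.9 ± 5.91 CPM in knockout (SD, n = 5 each; log2 fold change 0.83, edgeR adjusted p = 0.141). Foxm1, a transcription factor of mitotic genes, had a log2 fold change of 0.68 (SE 0.11, edgeR adjusted p = 0.141). Values of 0.73 for Hmmr and 0.77 for Kif20a, which act on the spindle and in cytokinesis, had edgeR adjusted p-values of 0.143 for both. The groups did not overlap for these 4 genes, nor for 14 of the 40 members in all. Without knockout replicate 5 edgeR called 7 members over all genes, among them Prc1, Foxm1, Hmmr and Kif20a (adjusted p of 0.0329, 0.0335, 0.0329 and 0.0440). Mki67, the common marker of cycling cells, had a log2 fold change of 0.54 (SE 0.20, edgeR adjusted p = 0.344) and lay above the wild-type mean in 5 of 5 knockout libraries.

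Genes of DNA replication and the G1/S transition had smaller differences, which were not tested against those of mitotic genes. Of 43 measured members 28 were higher and 15 lower, with a median log2 fold change of 0.13. The list passed camera with the preset correlation (adjusted p = 0.0403) and had an adjusted p = 0.700 with an estimated correlation. Its call was lost without wild-type replicates 1, 2 and 4 (adjusted p of 0.193, 0.420 and 0.121) and without knockout replicates 1, 4 and 5 (0.0628, 0.105 and 0.452). By edgeR, 0 of its genes passed over all genes or adjusted over the list alone; 6 had an unadjusted p under 0.05, all higher, and DESeq2 called 1. Pole, the catalytic subunit of DNA polymerase epsilon, had a log2 fold change of 0.66 (SE 0.18, edgeR adjusted p = 0.236), and Hells, a chromatin remodeller of replicating cells, 0.54 (SE 0.16, adjusted p = 0.274). Ccnd1, which encodes the G1 cyclin D1, was at 261 ± 52.8 CPM in wild type and 230 ± 51.5 CPM in knockout (SD, n = 5 each; edgeR adjusted p = 0.662).

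Cell cycle inhibitors went both ways. Of 14 genes 7 were higher and 7 lower, and the list did not pass (camera adjusted p = 0.974). With edgeR, 0 passed over all genes and 2 passed adjusted over the list alone, 1 in each direction; 5 had an unadjusted p under 0.05, and DESeq2 called 2. Cdkn1b, which encodes p27, had a log2 fold change of 0.47 (SE 0.12, edgeR adjusted p = 0.234). Cdkn2a, whose products p16 and p19ARF restrain the cycle and mark ageing cultures, was at 85.6 ± 28.4 CPM in wild type and 45.6 ± 6.29 CPM in knockout, with no overlap (SD, n = 5 each; log2 fold change -0.91, edgeR adjusted p = 0.231). The value for Cdkn1a, which encodes p21, was -0.27 (SE 0.14, adjusted p = 0.411). Targets of p53 were lower as a list, with 19 of 24 members below 0 and a median of -0.19 (camera adjusted p = 0.00166). Their adjusted p = 0.460 with an estimated correlation, and camera gave 0.0528 without knockout replicate 5 (0.0772 with the length and GC offset as well). Adjusted over the list alone 3 of them were lower by edgeR, against 0 over all genes; 3 had an unadjusted p under 0.05, and DESeq2 called 2. Perp, a p53 target of cell adhesion, had a log2 fold change of -1.11 (SE 0.25, edgeR adjusted p = 0.210), and Mdm2, which marks p53 for degradation, -0.50 (SE 0.13, adjusted p = 0.234).

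**Figure D2:**
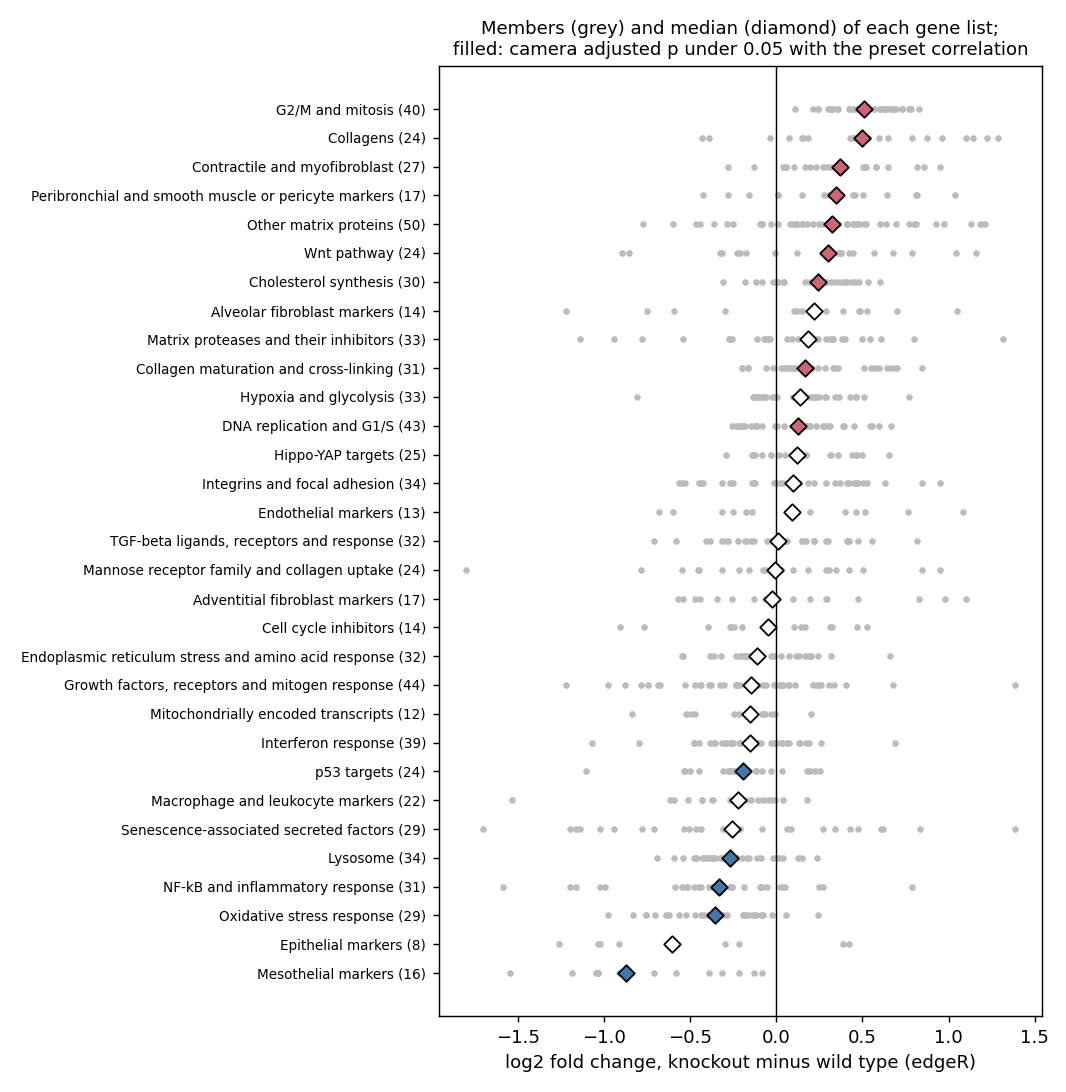
Log2 fold change (knockout over wild type) of each measured member of the 31 gene lists (points) and the median of each list (diamonds, filled where camera with the preset correlation gave an adjusted p under 0.05). All 40 genes of the G2/M and mitosis list and all 16 mesothelial markers lie on one side of 0, and 0 of the lists passed with an estimated correlation.

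Collagen genes were higher in 4 of the 5 knockout libraries. Of 24 measured collagen genes 21 had a log2 fold change above 0, and the median was 0.50 (1.41-fold). The list rose by camera with the preset correlation (adjusted p = 3.3e-06), with adjusted p = 0.460 with an estimated correlation and an exact permutation p of 0.0635 for its score (two-sided). Adjusted over the list alone 7 collagens were higher by edgeR and 0 over all genes; 9 had an unadjusted p under 0.05, and DESeq2 called 3. The mean score of the list was 0.31 to 0.69 in knockout replicates 1 to 4 and -0.44 in replicate 5, within the wild-type range of -0.54 to 0.00. Leaving out knockout replicate 5 brought 4 collagens past edgeR's test over all genes, among them Col3a1, Col11a1 and Col5a1 (adjusted p of 0.0457, 0.0329 and 0.0329). Since this removes the knockout library with the lowest collagen score, it is no separate support. Col3a1, a fibrillar collagen of type III, was at 2399 ± 962 CPM in wild type and 5842 ± 2175 CPM in knockout (SD, n = 5 each; log2 fold change 1.28, SE 0.35, edgeR adjusted p = 0.243). The chains of type I collagen had values of 0.79 for Col1a1 (SE 0.25, adjusted p = 0.294) and 0.50 for Col1a2 (SE 0.21, adjusted p = 0.355). Each lay above the wild-type mean of log2 CPM in 5 of 5 knockout libraries. In CPM, Col1a2 in knockout replicate 5 (7024) lay just below the wild-type mean (7080). Col11a1 and Col5a1, chains of collagens that nucleate fibrils, had values of 0.96 (SE 0.20, adjusted p = 0.208) and 0.88 (SE 0.20, adjusted p = 0.229).

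Other matrix genes and the enzymes of collagen maturation leaned the same way. Of 50 other matrix genes 39 were higher, with a median of 0.32 (camera adjusted p = 5.3e-05; adjusted p = 0.460 with an estimated correlation). Fn1, which encodes fibronectin, had a log2 fold change of 0.97 (SE 0.30, edgeR adjusted p = 0.282) and Vcan, the proteoglycan versican, 1.21 (SE 0.37, adjusted p = 0.282). Ltbp4, which stores latent TGF-beta in the matrix, had no overlap between groups (0.64, SE 0.13, adjusted p = 0.146). Adjusted over the list alone 1 of these genes was higher by edgeR and 0 over all genes; 11 had an unadjusted p under 0.05, and DESeq2 called 2. Among 31 genes of collagen maturation and cross-linking 25 were higher, with a median of 0.17 (camera adjusted p = 0.00116; adjusted p = 0.460 with an estimated correlation). Loxl3, a lysyl oxidase that cross-links collagen, was at 164 ± 9.12 CPM in wild type and 248 ± 41.5 CPM in knockout (SD, n = 5 each; edgeR adjusted p = 0.188), and Adamts2, which trims procollagen, had a log2 fold change of 0.70 (SE 0.22, adjusted p = 0.287). In this list 1 gene was higher by edgeR when adjusted over the list alone and 0 over all genes; 8 had an unadjusted p under 0.05, and DESeq2 called 1. Knockout replicate 5 lay within the wild-type range for both lists, with scores of -0.27 for other matrix genes (other knockout libraries 0.17 to 0.41) and -0.19 for maturation (others 0.14 to 0.24). Without knockout replicate 5 edgeR called 4 of the other matrix genes, among them Fn1 and Vcan (adjusted p of 0.0329 and 0.0440), and 2 of the maturation genes, among them Loxl3 (0.0329).

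Matrix proteases and the collagen uptake pathway did not move as groups. Of 33 proteases and inhibitors 20 were higher (median 0.18, camera adjusted p = 0.269). Adjusted over the list alone 2 were higher by edgeR and 0 over all genes; 5 had an unadjusted p under 0.05, and DESeq2 called 2. Adam12, a membrane protease of activated fibroblasts, was at 60.9 ± 20.2 CPM in wild type and 152 ± 44.9 CPM in knockout with no overlap (SD, n = 5 each; log2 fold change 1.32, edgeR adjusted p = 0.166, and 0.0329 without knockout replicate 5). Mmp3, which encodes stromelysin, had a value of -1.14 (SE 0.47, adjusted p = 0.354). Mmp2 and Mmp14, which cleave collagens and gelatin, had values of 0.33 (SE 0.50, adjusted p = 0.767) and -0.07 (SE 0.20, adjusted p = 0.884), and the sign turned to -0.48 for Mmp2 without knockout replicate 1 and to 0.04 for Mmp14 without wild-type replicate 3. In the list of mannose receptors and collagen uptake 12 of 24 genes were higher and 12 lower (median -0.01, camera adjusted p = 0.540), and its direction turned without knockout replicate 5 (adjusted p = 0.872). Mrc2 was the 1 member that passed, both over all genes and adjusted over the list alone. Mfge8, which bridges collagen to phagocytes, had a log2 fold change of -0.45 (SE 0.14, edgeR adjusted p = 0.287), and the collagen-binding integrin gene Itga1 0.85 (SE 0.28, adjusted p = 0.310).

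Lysosomal genes were lower in knockout as a group. Of 34 members 28 had a log2 fold change below 0, and the median was -0.27 (0.830-fold; camera adjusted p = 2.0e-06). The adjusted p = 0.460 with an estimated correlation, and the exact permutation p of the score was 0.0635 (two-sided). Adjusted over the list alone 5 genes were lower by edgeR and 0 over all genes; 14 had an unadjusted p under 0.05, and DESeq2 called 5. Lamp1, an abundant protein of the lysosomal membrane, was at 1173 ± 95.8 CPM in wild type and 885 ± 74.2 CPM in knockout with no overlap (SD, n = 5 each; log2 fold change -0.41, edgeR adjusted p = 0.258). Atp6v0d1, a subunit of the proton pump that acidifies lysosomes, had a value of -0.54 (SE 0.14, adjusted p = 0.234), and was 1 of 2 members that edgeR called without knockout replicate 5 (adjusted p = 0.0457). The collagen-degrading cathepsin K gene, Ctsk, had -0.11 (SE 0.23, adjusted p = 0.838) and the cathepsin B gene, Ctsb, -0.40 (SE 0.22, adjusted p = 0.436). Macrophages are rich in lysosomes, and wild-type replicate 5 had both the highest score of leukocyte markers (1.12) and the highest lysosome score (0.39) of the 10 libraries.

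Genes of the oxidative stress response were lower in 5 of 5 knockout libraries. Of 29 members 27 had a log2 fold change below 0, with a median of -0.35 (0.782-fold; camera adjusted p = 6.3e-06). The adjusted p = 0.460 with an estimated correlation. The score of every knockout library lay below that of every wild-type library, and the exact permutation p of 0.00794 (two-sided; adjusted p = 0.197) is the smallest that 5 against 5 can give. Adjusted over the list alone 3 genes were lower by edgeR and 0 over all genes; 10 had an unadjusted p under 0.05, and DESeq2 called 3. Hmox1, which encodes heme oxygenase, was at 1488 ± 424 CPM in wild type and 756 ± 263 CPM in knockout (SD, n = 5 each; log2 fold change -0.98, edgeR adjusted p = 0.241). Prdx6, a peroxiredoxin, had a log2 fold change of -0.64 (SE 0.18, adjusted p = 0.243). The value for Gstm1, a glutathione transferase whose close relatives could share some of its reads, was -0.76 (SE 0.17, adjusted p = 0.210). Without knockout replicate 5 edgeR called 4 members, among them Gstm1 and Hmox1 (adjusted p of 0.0439 and 0.0483).

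**Figure D3:**
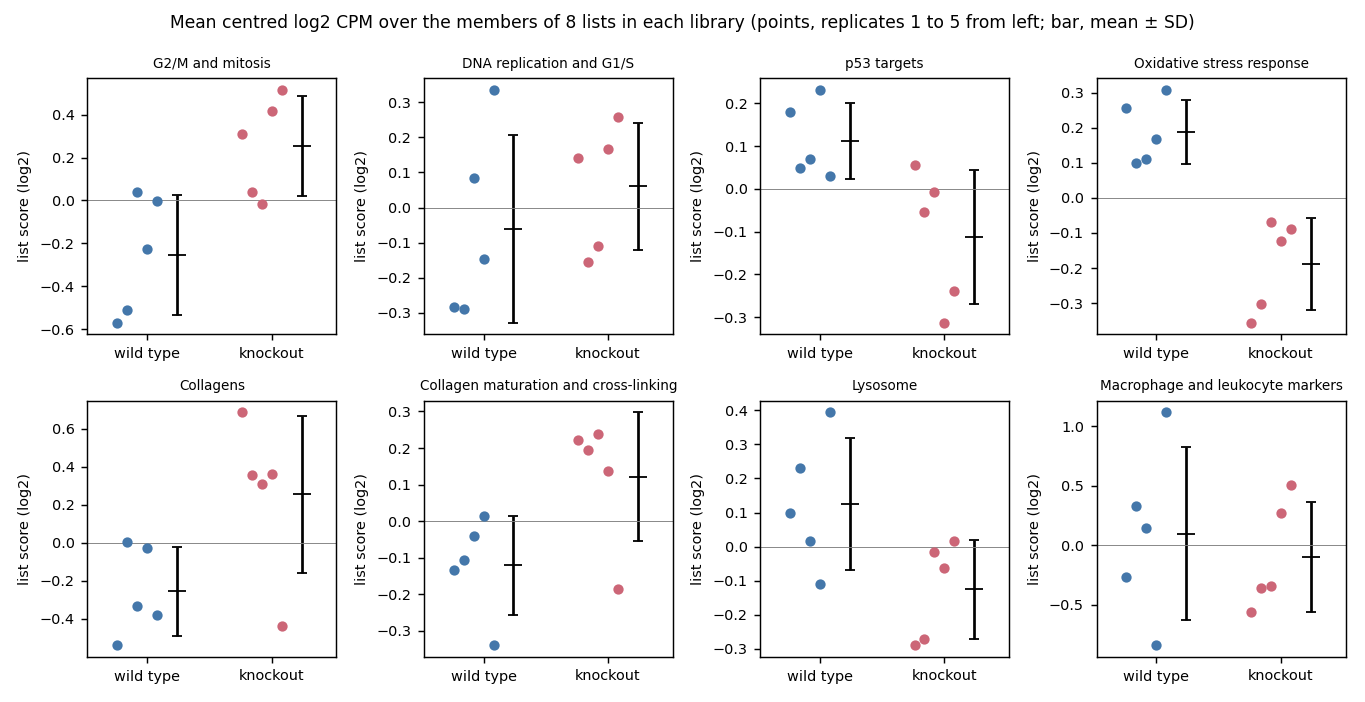
Mean score of 8 gene lists in each library (points, log2 CPM relative to the mean over all 10 libraries), with wild type and knockout apart. Knockout replicate 5 has the highest G2/M and mitosis score of all libraries (0.52) and a collagen score of -0.44, below the other 4 knockout libraries.

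Contractile genes were higher in knockout, with 25 of 27 above 0 and a median of 0.37 (camera adjusted p = 4.6e-06; adjusted p = 0.460 with an estimated correlation). With edgeR, 0 passed over all genes or adjusted over the list alone; 7 had an unadjusted p under 0.05, all higher, and DESeq2 called 3. The log2 fold change was 0.65 for Myh10 (SE 0.18, edgeR adjusted p = 0.243) and 0.40 for Myh9 (SE 0.13, adjusted p = 0.294), which encode non-muscle myosins, and 0.52 for the actin cross-linker Flna (SE 0.16, adjusted p = 0.274). The myofibroblast marker Acta2 was at 5479 ± 2531 CPM in wild type and 6620 ± 1842 CPM in knockout, a difference within the spread between replicates (SD, n = 5 each; edgeR adjusted p = 0.683). Markers of peribronchial fibroblasts, smooth muscle and pericytes were higher in 14 of 17 cases, with a median of 0.34 (camera adjusted p = 0.0224; adjusted p = 0.460 with an estimated correlation), and camera gave 0.196 without wild-type replicate 2 and 0.0528 without knockout replicate 5. By edgeR 0 of them passed over all genes or adjusted over the list alone; 4 had an unadjusted p under 0.05, and DESeq2 called 0. They include Myh11, the smooth muscle myosin (0.82, SE 0.33, adjusted p = 0.350), and Notch3, a receptor of mural cells (1.03, SE 0.34, adjusted p = 0.306).

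Of 5 signalling lists camera with the preset correlation called 1, the Wnt list. Of 32 genes of TGF-beta signalling 18 were higher (median 0.01, camera adjusted p = 0.399). Among them were Ldlrad4, an inhibitor induced by the pathway (0.82, SE 0.21, edgeR adjusted p = 0.234, and 0.0332 without knockout replicate 5), and Inhba, which encodes activin A (0.56, SE 0.17, adjusted p = 0.284). Of 44 growth factor and mitogen response genes 28 were lower (median -0.15, camera adjusted p = 0.106), and the list passed without knockout replicate 2 (adjusted p = 0.0385), without knockout replicate 3 (0.0358), and with the Y-linked (0.0215), surrogate (0.0194), length slope (0.0209) or leukocyte (0.0377) covariate. Fgf10, a growth factor for alveolar epithelium, had a log2 fold change of -1.22 (SE 0.35, edgeR adjusted p = 0.258) and Kitl, the ligand of Kit, -0.97 (SE 0.30, adjusted p = 0.285). The fibroblast receptor gene Pdgfra had 0.41 (SE 0.24, adjusted p = 0.454). Integrin and focal adhesion genes had a median of 0.10, with 20 of 34 higher (camera adjusted p = 0.238). Hippo-YAP targets had a median of 0.12, with 18 of 25 higher (camera adjusted p = 0.0614), and passed without wild-type replicate 4 (adjusted p = 0.00368), without knockout replicate 4 (0.0211) and with no low-count filter (0.0341). The Wnt list was higher in 16 of 24 genes, with a median of 0.30 (camera adjusted p = 0.0496; adjusted p = 0.595 with an estimated correlation). Its call was lost without wild-type replicates 2, 3 and 5 (0.147, 0.0784 and 0.208) and without knockout replicates 1, 2, 3 and 4 (0.0935, 0.142, 0.233 and 0.0727). It was also lost with RLE size factors (0.0543), DESeq2 (0.0543), no low-count filter (0.0847), the stricter filter (0.0608), sample quality weights (0.132), the Y-linked (0.209), surrogate (0.430), length slope (0.401) or leukocyte (0.134) covariate, without chromosome 11 (0.0711) and without the 3 libraries of lowest length slope (0.0784). The Wnt co-receptor Lrp6 had a log2 fold change of 0.57 (SE 0.18, edgeR adjusted p = 0.298) and the receptor Fzd4 0.68 (SE 0.26, adjusted p = 0.344). With edgeR, 0 genes of these 5 lists passed over all genes or adjusted over the list alone. At an unadjusted p under 0.05 the counts were 4 for TGF-beta, 8 for growth factors, 5 for integrins, 4 for Hippo-YAP and 2 for Wnt, and DESeq2 called 1, 1, 0, 0 and 0.

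Markers of alveolar and adventitial fibroblasts were not called as lists. Of 14 alveolar fibroblast markers 10 were higher, with a median of 0.22 (camera adjusted p = 0.255). Npnt passed as higher and Fgf10 as lower when adjusted over the list alone by edgeR, and 0 over all genes; 4 had an unadjusted p under 0.05, DESeq2 called 2, and edgeR called Npnt without knockout replicate 5 (adjusted p = 0.0329). Of 17 adventitial markers 8 were higher and 9 lower. Their median was -0.03, and their mean of 0.08 and the direction of the test lay above 0 (camera adjusted p = 0.730), which turned without knockout replicate 1 (adjusted p = 0.578). Cygb, which encodes cytoglobin, was the 1 adventitial marker higher by edgeR when adjusted over the list alone (log2 fold change 0.98, SE 0.23, adjusted p = 0.231 over all genes), with 0 over all genes; 2 had an unadjusted p under 0.05, and DESeq2 called 1. Without knockout replicate 5 edgeR called 2 adventitial markers, among them Cygb (adjusted p = 0.0483).

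Transcripts of other cell types were present in both groups. Some leukocyte markers were abundant. Lyz2, which encodes lysozyme, was at 5297 ± 2910 CPM in wild type and 3454 ± 1317 CPM in knockout (SD, n = 5 each, edgeR adjusted p = 0.480). Spp1, which macrophages and some fibroblasts express, was at 6695 ± 3306 and 4432 ± 1621 CPM (SD, n = 5 each, edgeR adjusted p = 0.459). Of 30 listed leukocyte markers 22 passed the low-count filter. Of 22 leukocyte markers 20 were lower, with a median of -0.22 (camera adjusted p = 0.241). The list passed without wild-type replicate 4 (adjusted p = 0.00280), and its direction turned without wild-type replicate 5 (adjusted p = 0.484). Mesothelial markers were all lower, 16 of 16, with a median of -0.87 (0.547-fold; camera adjusted p = 0.00162). The adjusted p = 0.595 with an estimated correlation, the exact permutation p of the score was 0.175 (two-sided), and camera gave 0.0528 without knockout replicate 5 (0.154 with the length and GC offset as well). Msln, which encodes mesothelin, was at 14.3 ± 10.9 CPM in wild type and 4.87 ± 4.16 CPM in knockout (SD, n = 5 each; edgeR adjusted p = 0.354). Of 8 epithelial markers 6 were lower (median -0.60, camera adjusted p = 0.241), and of 13 endothelial markers 7 were higher (median 0.09, camera adjusted p = 0.776; the direction turned without wild-type replicate 3, adjusted p = 0.916). With edgeR, 0 genes of these 4 lists passed over all genes or adjusted over the list alone. At an unadjusted p under 0.05 the counts were 1 leukocyte, 3 mesothelial, 2 epithelial and 3 endothelial markers, and DESeq2 called 0 in each list.

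The libraries also differed in how their values depended on gene length. The first principal component of log2 CPM held 38.0% of the variance. It followed the slope of each library's values on gene length over the 10 libraries, the only relation of this kind computed. Pearson r was 0.993 (permutation p = 1e-05, the smallest that the permutations can give) and Spearman rho 0.988 (permutation p = 3e-05). Without the 2 libraries farthest from the median slope r was 0.989. Both measures come from the same log2 CPM values, so some relation is built in and these p-values give no separate support. The slope on GC content was 1.44 in knockout replicate 5, lowest on the component (-45.5). It was -1.17 in knockout replicate 1, the highest (44.3). Length and GC content are therefore not told apart here. Across genes the loading on this component correlated with log2 gene length at 0.436, and the length and GC trend held 0.372% to 15.3% of the variance of each library around the mean of the 10. The slope was -0.04 ± 0.09 log2 units per doubling of length in wild type and 0.04 ± 0.12 in knockout (SD, n = 5 each; exact permutation p = 0.230, two-sided). Knockout replicate 5 had a slope of -0.16, below the lowest wild-type value of -0.15, and wild-type replicate 2 one of 0.09, among the knockout values. The mitotic, collagen and lysosomal differences stood beside this trend, and with the length and GC trend of each library removed the score differences between knockout and wild type were 0.48, 0.38 and -0.24.

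**Figure D4:**
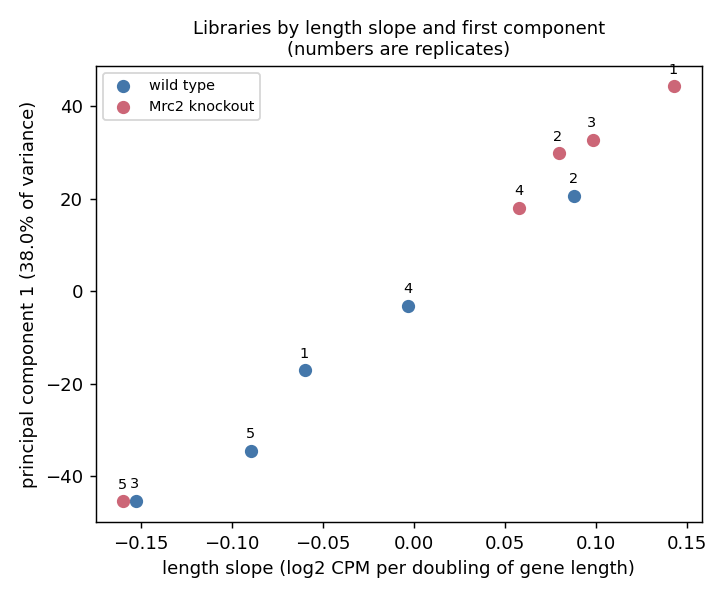
Slope of each library's log2 CPM on gene length (x axis, log2 units per doubling of length) against the first principal component (y axis, 38.0% of the variance), with replicate numbers, for wild type and knockout. Knockout replicate 5 lies beside the lowest wild-type library at a slope of -0.16 and wild-type replicate 2 among knockout libraries at 0.09.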

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

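The counts of splits and the test of mesothelial markers were chosen before their results were seen; the tests of exchanged labels, of the length and GC trend and of leukocyte markers, the splits with Mrc2 taken out, and the use of sample quality weights, were chosen after the result was seen. A library was singled out when its gap to the nearest other library of its group was too large for the group's range by Dixon's 95% criterion for 5 samples. Over 220 groups of 5 values 20 passed, where chance gives about 1 in 20, or 11, and 11 of the 20 lay in knockout replicate 5.

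Knockout replicate 5 had the lowest log2 CPM of its group for the matrix and receptor genes Col3a1 (11.1, others 12.4 to 12.9), Fn1 (11.8, others 13.1 to 13.6) and Pdgfra (6.16, others 7.20 to 7.46), and for Ccnd1 (7.15, others 7.88 to 8.10), Kitl (2.84, others 3.84 to 4.23), Slc7a5 (7.08, others 7.34 to 7.42) and Fzd4 (5.36, others 6.09 to 6.16). Ccl2 was highest in that library (6.78, others 6.14 to 6.32). Its score for collagen maturation was -0.187 (others 0.138 to 0.238), its 10 most abundant genes took 7.89% of counts (others 9.29% to 9.81%), and its length slope was -0.160 (others 0.0577 to 0.143). Knockout replicate 1 had low Cdkn2a (5.12, others 5.55 to 5.68), Krt18 (1.121, others 2.69 to 3.10) and Mmp3 (4.57, others 7.10 to 7.89) and high Mmp2 (8.48, others 6.04 to 6.33), all as log2 CPM. Aqp5 was high in knockout replicate 3 (0.0567, others -0.548 to -0.468). Atp6v0d1 was low in wild-type replicate 2 (7.25, others 7.64 to 7.74), whose total of 29362649 reads was above the others' 19603933 to 22122204. Col11a1 was high in wild-type replicate 3 (6.76, others 5.88 to 6.12), and Fzd4 was low in wild-type replicate 5 (4.07, others 5.36 to 5.62).

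The first pattern is that wild-type replicate 2 and knockout replicate 5 lie with the other group. Of 100 splits of the 10 libraries, the one in which these 2 libraries trade places called 4991 genes by edgeR against 2 for the real split, which points to a structure of the samples other than genotype. Exchanged labels are argued against by Mrc2 itself, at 231 CPM in knockout replicate 5 and 952 CPM in wild-type replicate 2. A transcript length and GC trend is argued against as the whole cause, since 3226 genes were still called in that split with each library's trend removed. Culture density and handling stay open and were not tested, and the design gives no biological group that would set these 2 libraries apart. Growth state is argued against only as far as mitotic genes show it. Their score was 0.515 in knockout replicate 5 and -0.509 in wild-type replicate 2, each on the side of its own group. Other aspects of growth state were not tested. The library name of knockout replicate 5 falls outside the consecutive run of the other knockout names, and the wild-type names form a separate run. What these names stand for is not given. Since the names divide by genotype, whatever they stand for cannot be told apart from it.

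The second pattern is the raised mitotic genes, with a score difference of 0.508 (SE 0.163) on the log2 scale. It was 0.476 (SE 0.181, exact permutation p = 0.0397) with the length and GC trend removed, 0.548 (SE 0.154) with the leukocyte score and 0.432 (SE 0.189) with the mesothelial score as a covariate, so none of these accounts for most of it. Chance is not excluded by the splits: 7 of 100 gave the list a camera p as small as the real 4.2e-22, and the smallest other was 5.6e-37. In the split in which wild-type replicate 2 and knockout replicate 5 trade places the p was 0.207, so the mitotic genes did not follow that structure. Loss of Mrc2 and the growth state of the cultures both stay open, untested.

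The third pattern joins higher collagen and lower lysosomal genes. The collagen score difference of 0.510 (SE 0.213) was 0.384 (SE 0.147, exact permutation p = 0.0397) with the length and GC trend removed and 0.458 (SE 0.202) with the leukocyte covariate. The lysosome difference of -0.251 (SE 0.108) was -0.236 (SE 0.104, exact permutation p = 0.0635) and -0.204 (SE 0.059), so neither the trend nor leukocytes account for most of either. Unlike the mitotic score, the collagen score went in part with the structure of the first pattern. Knockout replicate 5 had the lowest knockout score (-0.436), which lay among the wild-type values. Wild-type replicate 2 had the highest wild-type score (0.003), but it lay near wild-type replicate 4 (-0.029) and below knockout replicates 1 to 4 (0.308 to 0.686). That structure stays open for the collagen difference. For camera calls as a whole chance is not excluded, since 21 of 100 splits called at least the real 14 lists, and the highest other split called 21. Genotype stays open among explanations that were not tested further.

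For the counts of genes, 2 of 100 splits, the real one included, gave at least 2 genes by edgeR. The real count is led by Mrc2, the gene by which the groups are labelled, so this comparison decides nothing about chance. It also says nothing about a response to the loss of Mrc2. The other split was the one described above with 4991. With Mrc2 taken out before the adjustment the real split called 0 genes, a count that all 100 of 100 splits must reach (highest other 4991), so the splits decide nothing about other genes. Without knockout replicate 5, 2 of 100 splits of the 9 libraries gave at least the real 203 genes (highest other 4023), which decides nothing about chance, since that library was singled out for its effect on this count. By DESeq2 10 of 100 splits gave at least the real 243 genes (highest other 5641), and with sample quality weights 7 of 100 gave at least the real 4704 (highest other 5183), so chance is not excluded for either count.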

How the results depend on the processing

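The length, GC, leukocyte and sample-weight settings, the permutation of list scores and the 3 libraries left out together were chosen after the data were seen; the other settings were planned. In the settings that kept Mrc2 its direction never turned, with log2 fold changes of -1.73 to -1.93. The G2/M and collagen lists kept their direction and their camera call in every refit with the preset correlation, and over all settings 3464 gene values and 772 list values kept their direction and side of the threshold, 189 and 34 passed it that had not, 16 and 82 lost it, and 35 and 41 turned. Depth limits genes at 0.153 CPM or less, where a library can hold 3 counts or fewer; whether more reads would add calls was not tested. Scaling moved the median log2 fold change of all genes by less than 0.1. Where no reason is given the cause was not tested.

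DESeq2 called 243 genes (146 higher, 97 lower) and limma-voom 1 (1 lower). With sample quality weights limma called 4704 (2366 higher, 2338 lower), with the lowest weights in knockout replicate 5 (0.231) and wild-type replicate 2 (0.441). Counts were 1 (1 lower) with the Y-linked covariate, 1 (1 lower) with the length and GC offset, 2 (2 lower) with the surrogate variable and 4 (4 lower) with the length slope as a covariate, all 4 fits without Crct1, and 6 (3 higher) with the 3 libraries of lowest slope left out. The length and GC offset without knockout replicate 5 gave 32 (20 higher, 12 lower). Without chromosome 11, which removes Mrc2 itself, edgeR called 0 (0 lower; 1743 with an unadjusted p under 0.05). Leaving out single libraries gave 1 to 203 genes, 0 to 129 higher and 1 to 74 lower, with all highest values without knockout replicate 5.

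No pairing by replicate number is stated, and a check on 5 pairs cannot exclude one. The deviations of same-numbered libraries correlated at -0.236 to 0.376, over 0.1 for 2 of 5 pairs. In each group 1 library correlated best with its own number. With the replicate block edgeR called 0 genes (0 lower; 1913 with an unadjusted p under 0.05), and Mrc2 had a log2 fold change of -1.78 (adjusted p = 0.0542), with fewer residual degrees of freedom. In that block fit the G1/S list had a camera adjusted p of 0.0848, Pla2r1 was at -0.02, and the cell cycle inhibitors turned (0.967).

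For lists, adjusted p-values with an estimated correlation were 0.460 for G2/M, 0.460 for collagens and 0.700 for G1/S. By fry they were 0.0929, 0.189 and 0.598, and by exact permutation of list scores 0.197, 0.197 and 0.609. G1/S also missed the threshold with the stricter filter (0.0528), sample quality weights (0.180), without chromosome 11 (0.0711) and with the offset without knockout replicate 5 (0.475). Its range over single libraries left out was 5.3e-05 to 0.452.

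Some lists turned direction without being called, given here by adjusted p. Cell cycle inhibitors turned with upper-quartile scaling (0.995), the stricter filter (0.959), sample quality weights (0.992), the Y-linked covariate (0.948), the surrogate variable (0.989), without chromosome 11 (0.811), the length and GC offset (0.651), the 3 libraries left out (0.907) and the offset without knockout replicate 5 (0.475). Adventitial markers turned by permutation (0.905), with the Y-linked covariate (0.948), without chromosome 11 (0.811) and with the length slope (0.992). Endothelial markers turned with the stricter filter (0.691), sample quality weights (0.992), the Y-linked covariate (0.966), the surrogate variable (0.989), the length slope (0.992) and the offset without knockout replicate 5 (0.948). Leukocyte markers turned with the Y-linked covariate (0.948), the surrogate variable (0.812), the length slope (0.943) and the 3 libraries left out (0.880); they were not refitted with their own score as a covariate. Alveolar markers turned with the surrogate variable (0.989) and the length slope (0.992). The stress and amino acid list turned with the Y-linked covariate (0.818), the surrogate variable (0.610) and the length slope (0.590). The mannose receptor list turned without chromosome 11 (0.856), which removes Mrc2. Ranges over single libraries left out were 0.677 to 0.983 for inhibitors, 0.384 to 0.944 for adventitial, 0.667 to 0.954 for endothelial, 0.00280 to 0.615 for leukocyte, 0.192 to 0.761 for stress, 0.302 to 0.872 for mannose receptor and 0.00118 to 0.845 for interferon genes.

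Some genes turned sign, given here as log2 fold changes. Pla2r1 was at -0.022 with upper-quartile scaling, -0.026 with library size only, -0.007 with the stricter filter, -0.011 with limma-voom, -0.029 with sample quality weights, -0.28 with the Y-linked covariate, -0.34 with the surrogate variable, -0.20 with the length and GC offset, -0.33 with the length slope, -0.027 with the 3 libraries left out, -0.12 with the leukocyte covariate and -0.10 with the offset without knockout replicate 5. Mmp2 was at -0.042 with sample quality weights, -0.073 with the Y-linked covariate and -0.018 with the length slope. Mmp14 was at 0.057 with the Y-linked covariate, 0.08 with the surrogate variable and 0.094 with the length slope. Ctsk was at 0.039 with the surrogate variable and 0.03 with the length slope. Mrc1 was at 0.125 with sample quality weights and 0.043 with the 3 libraries left out. Ranges over single libraries left out were -0.14 to 0.16 for Pla2r1, -0.48 to 0.70 for Mmp2, -0.19 to 0.04 for Mmp14 and -0.44 to 0.16 for Mrc1.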

Other observations

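The neighbours of Crct1 and the epithelial genes below were looked at after the values of Crct1 and Ivl were seen. The list of NF-kB and inflammatory genes was lower in 25 of 31 members, with a median log2 fold change of -0.33 (camera adjusted p = 0.00355; adjusted p = 0.460 with an estimated correlation). Wild-type replicate 5 had the highest score of the 10 libraries for this list (0.55) and for leukocyte markers (1.12), and with the leukocyte score as a covariate the NF-kB and inflammatory response list had a camera adjusted p of 0.00832. By edgeR 2 of its genes were lower when adjusted over the list alone and 0 over all genes; 6 had an unadjusted p under 0.05, and DESeq2 called 2. Ccl2, a chemokine for monocytes, was at 182 ± 93.3 CPM in wild type and 81.2 ± 16.3 CPM in knockout with no overlap (SD, n = 5 each; edgeR adjusted p = 0.231), and its neighbour Ccl7 had a log2 fold change of -1.20 (SE 0.30, adjusted p = 0.234, and 0.0407 without knockout replicate 5). Cxcl12, a chemokine that retains leukocytes, went the other way at 560 ± 133 and 998 ± 188 CPM with no overlap (SD, n = 5 each; edgeR adjusted p = 0.217). Of 29 senescence-associated secreted factors 19 were lower (median -0.26, camera adjusted p = 0.0784), and the list passed without wild-type replicate 3 (0.0310), without knockout replicate 3 (0.0318), with no low-count filter (0.0256), the replicate block (0.0285) or sample quality weights (0.0364), and without the 3 libraries of lowest length slope (0.0331). By edgeR 2 of them were higher and 3 lower when adjusted over the list alone and 0 over all genes; 7 had an unadjusted p under 0.05, and DESeq2 called 4. Interferon response genes were lower in 28 of 39 cases (median -0.15, camera adjusted p = 0.253), passed without wild-type replicate 3 (0.00118), with sample quality weights (3.1e-05) and without the 3 libraries of lowest length slope (7.9e-05), and turned direction without wild-type replicate 1 (0.801). By edgeR 0 of them passed over all genes or adjusted over the list alone; 1 had an unadjusted p under 0.05, and DESeq2 called 0.

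Of 4 lists of metabolism, stress and mitochondria camera with the preset correlation called 1, cholesterol synthesis. Cholesterol synthesis genes were higher in 24 of 30 cases (median 0.24, camera adjusted p = 0.00679; adjusted p = 0.606 with an estimated correlation), and the call was lost without wild-type replicate 5 (0.208), without knockout replicate 4 (0.0932), with the surrogate (0.145) or length slope (0.134) covariate, and without the 3 libraries of lowest length slope (0.105). By edgeR 0 of the list passed over all genes or adjusted over the list alone; 2 had an unadjusted p under 0.05, and DESeq2 called 0. Hypoxia and glycolysis genes had a median of 0.14, with 21 of 33 higher (camera adjusted p = 0.0807), and the list passed without wild-type replicates 1 and 3 (0.0316 and 0.0111), without knockout replicate 1 (3.1e-05), and with the Y-linked (0.00206), surrogate (0.00416) or length slope (0.00226) covariate. Ddit4, an inhibitor of mTORC1, had 0.77 (SE 0.19, edgeR adjusted p = 0.231, and 0.0498 without knockout replicate 5). By edgeR 0 of these genes passed over all genes or adjusted over the list alone; 4 had an unadjusted p under 0.05, and DESeq2 called 1. Of 32 genes of endoplasmic reticulum stress and amino acid response 21 were lower (median -0.11, camera adjusted p = 0.329), and the direction turned without wild-type replicate 3 (0.761). Slc7a5, a leucine transporter, was the 1 member higher by edgeR adjusted over the list alone, at 101 ± 17.2 and 160 ± 13.9 CPM with no overlap (SD, n = 5 each; adjusted p = 0.143 over all genes and 0.0415 without knockout replicate 5), with 0 over all genes; 3 had an unadjusted p under 0.05, and DESeq2 called 1. Mitochondrially encoded transcripts were lower in 11 of 12 cases (median -0.15, camera adjusted p = 0.0784), and passed without wild-type replicates 3 and 5 (0.0221 and 0.0243), without knockout replicates 2 and 4 (0.0280 and 0.0444), with the Y-linked (0.0189), surrogate (0.0159), length slope (0.0207) or leukocyte (0.0487) covariate, and without the 3 libraries of lowest length slope (0.00676). By edgeR 0 of them passed over all genes or adjusted over the list alone; 1 had an unadjusted p under 0.05, DESeq2 called 0, and edgeR without knockout replicate 5 called 1, mt-Nd3 (adjusted p = 0.0498).

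Within 1 Mb on each side of Crct1 on chromosome 3, which holds the epidermal differentiation complex, 9 other genes were tested, and 8 of them were lower in knockout. With an unadjusted p under 0.05, 4 were lower. No test of this share is given, since Crct1 and Ivl prompted the choice of the region. Those 4, named after their values were seen, were Ivl, Lce1g (log2 fold change -2.73, edgeR adjusted p = 0.143), Sprr1a (-0.98, adjusted p = 0.301) and Tchh (-0.65, adjusted p = 0.344), which encode proteins of cornified cells and hair. Aqp5, a water channel of alveolar and glandular epithelium encoded elsewhere, was chosen in the same way and stood at 2.81 ± 1.70 CPM in wild type and 0.685 ± 0.152 CPM in knockout (SD, n = 5 each; edgeR adjusted p = 0.143). Without knockout replicate 5 Lce1g and Aqp5 passed edgeR's test, with adjusted p-values of 0.0457 and 0.0497. Other epithelial genes went both ways by edgeR. Krt10 (0.31, adjusted p = 0.623) and Cdh1 (0.39, adjusted p = 0.633) had values above 0, but lay at 1.81 CPM or less in every library. The more abundant Krt7 (-1.26, adjusted p = 0.350), Krt8 (-0.91, adjusted p = 0.442) and Krt18 (-1.03, adjusted p = 0.417) had values below 0. Their means were 9.87, 13.1 and 13.0 CPM in wild type and 4.08, 6.94 and 6.36 CPM in knockout. Krt8 and Krt18 also stand in the list of mesothelial markers. Krt5, Krt14, Krt1 and Epcam were too low to test, at 0.420 CPM or less in every library.

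Genes near Mrc2 were examined because a knockout can carry linked alleles of another strain. Within 10 Mb on each side of Mrc2 0 of 262 other tested genes were called by edgeR, and 42 had an unadjusted p under 0.05, or 16.03% against 13.2% elsewhere (Fisher's exact p = 0.198, two-sided). With 5 and 20 Mb the shares were 14.3% and 13.9%, with p-values of 0.714 and 0.682.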
